A study of Mus musculus with 34 samples.

How the data were processed

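RNA sequencing of polyadenylated transcripts was analysed in 34 libraries of sorted mouse cells, 25 of fibroblasts from 9 tissues and 9 of mesothelial cells from 3 fat depots. Per the labels, tissues were digested, cells negative for CD45, CD31 and Epcam and positive for podoplanin were sorted into lysis reagent, and PDGFRA split fibroblasts (positive) from mesothelial cells (negative). Each deposited file holds whole-number read counts per gene for a single library, described per the file headers as reads that align uniquely to a gene model. The submitters' processing notes name Salmon, with no version, and the genome build GRCm38. Salmon estimates transcript abundance and the header speaks of unique alignment, so which step gave the deposited counts is unresolved. The annotation release, filters and any pooling are not stated. The values behaved as raw counts, being whole numbers whose totals differed between libraries. No entry lacked a gene identifier.

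Groups followed the labels, with 3 libraries each except 2 for pancreas and 2 for spleen fibroblasts. Of 51826 gene identifiers 51633 had a symbol in the gene name table and 193 had none. Positions of named genes come from the GENCODE M21 annotation of GRCm38, counted from 1. Total counts ran from 28.7 M to 42.3 M per library. Pairs of replicates were checked for copies of the same library. Over genes with a summed count of at least 20, the chi-square per degree of freedom between replicates ran from 24.8 to 359, far from the value near 1 that repeated sequencing of a single library gives.

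The main test was edgeR 4.0.16 in R 4.3.3, with its quasi-likelihood F-test (glmQLFit with robust estimation, without the legacy mode), TMM scaling and filterByExpr with a minimum count of 10 by group, which left 25705 genes. All 34 libraries entered a single fit with a coefficient per group, so that all groups share the estimate of spread. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1. The comparisons were mesothelial cells against fibroblasts in each of 3 depots and over their mean, the difference of these effects between depots, mesothelial cells between depots, fibroblasts across 9 tissues, visceral against subcutaneous fat fibroblasts, and each tissue's fibroblasts against the mean of the other 8. For tests over several groups the fold change is the range of the group effects. CPM values use library totals scaled by TMM, except sums over a list, which use unscaled totals. Against a side with no count, folds are lower bounds from 3 counts over that side. These bounds cover counting error only. Adjusted p-values measure only the spread between these libraries.

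Lists of genes were tested with camera in limma 3.58.1 on log CPM with a prior count of 2, at a preset correlation of 0.01 and with an estimated correlation, adjusted over the 425 tests of 25 lists in 17 comparisons. The lists covered mesothelial markers, fibroblast matrix, basement membrane, adipogenic, thermogenic, retinoid, lymphoid stroma, complement, myeloid growth factor and chemokine, Hox, regional transcription factor, skeletal and tendon, proliferation and immediate early genes, the sort markers, and markers of leukocytes, endothelium, epithelium, pancreatic acinar cells, erythroid cells, skeletal muscle, mural cells, Schwann cells and adipocytes. The lists, comparisons, tests and the rule for naming genes were written before the data were examined. By that rule the text names the sort markers; the called genes with the largest changes, 10 per direction for the mean mesothelial comparison and visceral against subcutaneous fat and 5 per direction otherwise, with at least 10 CPM on the higher side, no overlap of libraries between the sides and a gene symbol that is neither an accession nor a clone name, outside the lists of other cell types; up to 4 members of a list with the smallest adjusted p; and Wt1, Aldh1a1, Aldh1a2, Gata6 and Csf1. Where these made a paragraph too long, a part of them was left out.

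The test was first run on simulated counts drawn from the means and sizes of these libraries, with 50 genes changed at each of 4 fold sizes. Unlike in these data, a gene's mean was the same in all groups unless it was changed. Over 24336 genes the test recovered 0, 13, 37 and 42 of 50 genes at 1.5-fold, 2-fold, 4-fold and 8-fold for the mean mesothelial comparison, with 5 false calls. A 1.5-fold change lies below the required log2 fold change of 1 and a 2-fold change on it, so recovery at these sizes is limited by the threshold itself. For omentum against mesentery mesothelial cells, over 24339 genes, it recovered 22 of 50 at 4-fold and 29 at 8-fold with 6 false calls. For spleen fibroblasts, over 24337 genes, it recovered 1, 11, 33 and 38 at the 4 fold sizes, with 32 false calls. For lymph node fibroblasts, over 24319 genes, it recovered 0, 17, 29 and 39, with 23 false calls. In both tissue comparisons false calls thus made up a larger share of the calls than the adjusted p threshold allows. The other simulated comparisons gave 5 or 6 false calls each, a smaller share of the calls that still lay above the threshold. The remaining tissues were not simulated.

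Alternatives were RLE scaling, DESeq2 1.42.0, no filter on low counts, only the groups compared in the fit, a replicate block, and leaving out each library in turn. Alternatives planned in case the files held normalized values were not applicable. Chosen after seeing the data were fits without the 2 pancreas libraries, without libraries of at least 1000 acinar CPM, without bone replicates 1 and 2 together, and with marker genes of other cell types removed before scaling, and the list tests with a replicate block. Group labels of the compared libraries were also reassigned to other splits, at most 100 per comparison, with all libraries kept in the fit. Same-numbered libraries were checked for shared deviations from their group means over genes with a mean log2 CPM of at least 1. In 4 of 66 pairs of groups every same-number correlation exceeded 0.1, and the median over pairs of groups was 0.0207 for same-numbered and -0.0104 for other libraries. Among the groups compared directly, mesentery and epididymal mesothelial cells met that limit, with a lowest correlation of 0.147, a mean of 0.287 and 2 of 3 libraries closest to their own number. Omentum and mesentery fibroblasts, which enter the tissue comparisons and the test between depots, met it too, with a lowest correlation of 0.127 and a mean of 0.303. The labels do not say what the numbers share. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.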

Results

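The study sequenced polyadenylated RNA from stromal cells of mouse tissues to ask how transcription varies with the tissue that the cells live in. The 34 libraries fall into 12 groups. Fibroblasts, sorted as podoplanin-positive and PDGFRA-positive cells lacking CD45, CD31 and Epcam, came from 9 tissues, namely omentum, mesentery, epididymal fat, inguinal fat, brown adipose tissue, bone, lymph node, pancreas and spleen. Mesothelial cells, which line the body cavities and were sorted by the same gate but as PDGFRA-negative, came from 3 depots, the omentum, mesentery and epididymal fat. Each group held 3 libraries, except pancreas and spleen fibroblasts with 2 each. The labels class omentum, mesentery and epididymal fat as visceral fat, and inguinal and brown adipose tissue as subcutaneous fat. No label says whether the libraries of a group came from separate animals, so every p-value measures the spread between these libraries. Total counts per library ran from 28.7 M to 42.3 M with a median of 33.5 M (M, mega). By group, in M, they ran from 35.2 to 40 in omentum fibroblasts, 29.4 to 41.1 in mesentery, 28.8 to 34.6 in epididymal, 34.8 to 36.1 in inguinal, 35.2 to 42.3 in brown adipose, 30.9 to 32 in bone, 34 to 37.1 in pancreas, 28.7 to 33.3 in lymph node and 28.7 to 28.9 in spleen fibroblasts. In mesothelial cells the totals ran from 32.5 to 41 in the omentum, 30.7 to 33.6 in the mesentery and 29.2 to 34.6 in epididymal fat. Between 25783 and 34253 genes had a count in each library. Levels are given below in counts-per-million (CPM) as mean ± SD, and differences as log2 fold change ± SE from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. A gene counts as higher or lower at an adjusted p under 0.05 and an absolute log2 fold change of at least 1. Counts of list members are over all 25705 genes tested, and the count adjusted over the list alone is given where it differs.

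Transcripts of the sorted proteins followed the gate. Pdgfra (ENSMUSG00000029231, chromosome 5, 75152292 to 75198215), the receptor that separates the cell types, averaged 690 ± 65.8 CPM in omentum, 1195 ± 195 in mesentery and 1067 ± 69.6 in epididymal fibroblasts (n = 3 each). In the mesothelial cells of the same depots it averaged 11.7 ± 0.297, 6.61 ± 1.9 and 11.7 ± 1.66 CPM. Its lowest fibroblast mean was 394 ± 26.1 CPM in bone. Pdpn, which encodes podoplanin, averaged between 176 CPM in pancreas fibroblasts and 587 CPM in omentum mesothelial cells. Transcripts of the excluded markers were low, with Ptprc (CD45) at most 4.22 CPM, in omentum fibroblasts, Pecam1 (CD31) at most 26 CPM and Epcam at most 3.11 CPM, both in pancreas fibroblasts. As a list, the 5 sort markers passed no camera test among the 17 comparisons tested with lists, where their smallest adjusted p was 0.0609. Log expression values correlated with a median r of 0.966 over the 32 pairs of libraries of the same group. The median r was 0.947 over 27 pairs of mesothelial libraries from different depots, 0.919 over 277 pairs of fibroblast libraries from different tissues, and 0.873 over 225 pairs of a mesothelial with a fibroblast library. These are correlations across genes, which are not independent replicates. The leading principal component held 28.4% of the variance of log expression.

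Mesothelial cells of the 3 depots differed from the fibroblasts of the same depots in 5503 genes, 3168 higher and 2335 lower in mesothelial cells (n = 9 libraries each). The atrial myosin light chain gene Myl7 (8.57 ± 0.59), the proteoglycan gene Spock3 (7.92 ± 0.41), Vat1l (7.68 ± 0.32) and Mpzl2 (ENSMUSG00000032092, chromosome 9, 45039799 to 45054015, 7.48 ± 0.29, adjusted p = 1.75e-20) for an adhesion protein were among the largest rises. The fitted mean of Mybpc2 (8.55 ± 0.52) depends on the prior count, because mesentery fibroblasts had no count. The prostaglandin D synthase gene Ptgds (7.27 ± 0.41), the growth factor binding protein gene Igfbp2 (7.17 ± 0.35), Fam151a (7.14 ± 0.30) and Syngr1 (6.95 ± 0.42) followed, as did Krt18 (7.23 ± 0.45), whose keratin partner in simple epithelia, Krt8 (6.77 ± 0.35), was higher too. Among the largest falls were Pla1a (ENSMUSG00000002847, chromosome 16, 38396117 to 38433145, -10.34 ± 0.31, adjusted p = 2.63e-22) for a phospholipase, Hp (-10.12 ± 0.48) for haptoglobin and Srpx2 (-9.90 ± 0.19). The eosinophil chemokine gene Ccl11 (-9.27 ± 0.35), the enkephalin precursor gene Penk (-9.0 ± 0.29), the epithelial growth factor gene Fgf7 (-8.55 ± 0.28), and the matrix-associated Cilp (-8.82 ± 0.40) and Pcolce2 (-8.65 ± 0.18) fell with them. The methyltransferase gene Inmt (-9.27 ± 0.31) and the dipeptidase gene Dpep1 (-8.41 ± 0.18) fell as well. In each of these genes every mesothelial library lay beyond every fibroblast library.

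All 16 mesothelial markers were higher in mesothelial cells (camera adjusted p = 3.49e-17), including Krt7 (6.0 ± 0.23), Cldn15 (4.23 ± 0.18) and Nkain4 (4.07 ± 0.20). Of 16 fibroblast matrix genes, 7 were lower (adjusted p = 1.02e-09), with Lum (-5.74 ± 0.16), Fbn1 (-3.06 ± 0.14) and Col6a3 (-2.55 ± 0.12). Of 14 basement membrane genes 9 were lower, such as Col4a1 (-4.52 ± 0.16), Nid1 (-3.54 ± 0.13) and Lamc1 (-3.16 ± 0.15), and 3 were higher (adjusted p = 6.91e-05, and adjusted p = 0.222 with an estimated correlation). The adipogenic list was lower in 11 of 14 genes (adjusted p = 8.76e-09), led by the lipoprotein lipase gene Lpl (-7.20 ± 0.19), the preadipocyte factor Ebf2 (-7.75 ± 0.23) and Pparg (-5.27 ± 0.42), the master regulator of fat cell formation. Adipocyte markers moved the same way, 4 of 8 lower (adjusted p = 0.0186, and adjusted p = 0.259 with an estimated correlation), with Adipoq (-4.27 ± 0.57) at 1.02 CPM in omentum fibroblasts. Retinoid metabolism split into 4 higher and 6 lower of 19 genes (adjusted p = 0.338). Dhrs9 (5.28 ± 0.20) and the retinol uptake receptor Stra6 (4.15 ± 0.33) were higher, while Adh1 (-6.48 ± 0.20) and Aldh1a3 (-5.30 ± 0.16) were lower. Among 19 myeloid growth factors and chemokines 7 were lower and 3 higher, 4 adjusted over the list alone (adjusted p = 0.0181, and adjusted p = 0.353 with an estimated correlation). Cxcl12 (-6.25 ± 0.27) and Tslp (-4.31 ± 0.24) were lower and the stem cell factor gene Kitl (1.28 ± 0.10) was higher. Complement genes split, 3 higher and 2 lower of 12, with C2 (3.49 ± 0.10) and Cfb (2.04 ± 0.12) higher and Cd55 (-2.58 ± 0.11) lower, a median of -0.03 against a mean of 0.47 and a camera test that did not pass (adjusted p = 0.774). Of the regional transcription factors 8 were higher and 7 lower of 29, with Isl1 (4.95 ± 0.24) and Hand2 (2.69 ± 0.22) higher and Prrx1 (-4.55 ± 0.15) and Tcf21 (-5.53 ± 0.29) lower. Skeletal and tendon genes were lower in 7 and higher in 2 of 21 (adjusted p = 0.0146, and adjusted p = 0.134 with an estimated correlation). Epithelial markers were higher in 4 of 6 genes, with 1 lower when adjusted over the list alone, in a test that did not pass (adjusted p = 0.12). They included Krt14 (6.91 ± 0.47) and Epcam (2.08 ± 0.59), the latter at 0.478 CPM or less in the mesothelial groups. Of the list members named, only Epcam and Hand2 overlapped between mesothelial and fibroblast libraries.

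The mesothelial-fibroblast difference was then tested within each depot (n = 3 libraries per group). It covered 4342 genes in the omentum, 2082 higher and 2260 lower, 4701 in the mesentery, 2766 higher and 1935 lower, and 6358 in epididymal fat, 4261 higher and 2097 lower. The median log2 fold change over all genes was -0.09, 0.09 and 0.33 respectively, so the last split rests on values shifted upward as a whole. Fitted on the 6 epididymal libraries alone, the median there was 0.06. Without libraries of at least 1000 acinar CPM, an alternative chosen after the data were seen, the mesentery count was 2535. That fit leaves 1 mesothelial and 1 fibroblast library of the mesentery, so its counts and calls there rest on single libraries assumed to vary like the other groups. In all 3 depots 1256 genes were higher, against 37.1 if the lists were independent, and 971 were lower, against 13.9. A further 143 genes were higher in one depot and lower in another. Mesothelial markers were higher in 15 of 16 genes in the omentum and in 16 and 16 in the mesentery and epididymal fat (adjusted p = 1.43e-14, 1.45e-20 and 6.96e-16). The exception was Wt1 (ENSMUSG00000016458, chromosome 2, 105126529 to 105173616), the transcription factor of mesothelium and visceral mesenchyme, whose difference was 0.02 ± 0.30 in the omentum, where fibroblasts held 189 ± 5.6 CPM and mesothelial cells 192 ± 27.1. It was 2.27 ± 0.32 in the mesentery and 1.68 ± 0.31 in epididymal fat, and the test of the difference between depots gave an adjusted p of 0.00112. Aldh1a2 (ENSMUSG00000013584, chromosome 9, 71215789 to 71296243), which makes retinoic acid, had the same form, with 0.01 ± 0.40 in the omentum, 1.90 ± 0.41 in the mesentery and 3.31 ± 0.44 in epididymal fat (adjusted p between depots = 0.000961). It was not called in the mesentery without the libraries of at least 1000 acinar CPM, with 1 library left on each side (2.03, adjusted p = 0.128). Its relative Aldh1a1 differed by 0.91 ± 0.21, 0.45 ± 0.21 and 1.34 ± 0.21 (adjusted p = 0.102), and was called in the omentum only without mesothelial replicate 3 (1.08). Gata6, a transcription factor of mesodermal and endodermal tissues, was higher in mesothelial cells of each depot, by 1.65 ± 0.29, 1.93 ± 0.30 and 2.02 ± 0.30. Csf1, the macrophage growth factor, was lower in the omentum (-1.10 ± 0.35) and epididymal fat (-2.10 ± 0.36), while its mesentery value of -0.90 ± 0.35 did not pass (adjusted p = 0.0662, and 0.175 between depots). The omentum call was lost without fibroblast replicate 3 (adjusted p = 0.071) or mesothelial replicate 1 (adjusted p = 0.135), and the mesentery value passed without fibroblast replicate 1 (-1.23, adjusted p = 0.0082).

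The test between depots called Kcnip1, Galnt16, Cxcl13, Mybpc2, Cd74, Stmn4, Duoxa1, Clu, Il7, Il33 and Isl1 among the genes named next for single depots. It did not call Chrm2, Hp, Igkv12-89, Igha, Il6, Iyd, Insrr or Csf1r (adjusted p from 0.111 to 1). In the omentum Chrm2 (7.40 ± 0.67), a muscarinic receptor gene, and Kcnip1 (6.88 ± 0.51) were among the largest rises, and Galnt16 (-10.26 ± 0.50) and Hp (-9.50 ± 0.73) among the largest falls. Immunoglobulin transcripts were also among the falls there: Igkv12-89 and Igha had no count in the mesothelial libraries and were at least 1382-fold and 893-fold higher in fibroblasts. Beside them 4 of 16 leukocyte markers were lower, 9 adjusted over the list alone, in a list test that did not pass (adjusted p = 0.0515). Neither was called with DESeq2 (adjusted p = 0.166 and 0.192), nor was Igha when only the omentum libraries were fitted (adjusted p = 0.0675). The B cell attractant Cxcl13 (-5.41 ± 0.59) and the cytokine Il6 (-3.70 ± 0.53) were lower in omentum mesothelial cells than in omentum fibroblasts. In the mesentery the iodotyrosine deiodinase gene Iyd was at least 891-fold and Insrr at least 493-fold higher in fibroblasts, and Mybpc2 at least 1085-fold higher in mesothelial cells. The antigen presentation gene Cd74 (6.66 ± 0.96) and Csf1r (4.79 ± 0.78), both in the leukocyte list, were higher in mesentery mesothelial cells. In epididymal fat Stmn4 was at least 698-fold and Duoxa1 at least 609-fold higher in fibroblasts, and the lipoprotein Clu (6.69 ± 0.44), the cytokines Il7 (4.11 ± 0.39) and Il33 (2.51 ± 0.25) and Isl1 (7.36 ± 0.47) were higher in mesothelial cells. The size of the mesothelial-fibroblast difference varied between depots in 2812 genes. Without omentum fibroblast replicate 2 that count was 1767, and without omentum mesothelial replicate 2 it was 1828.

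**Figure D1:**
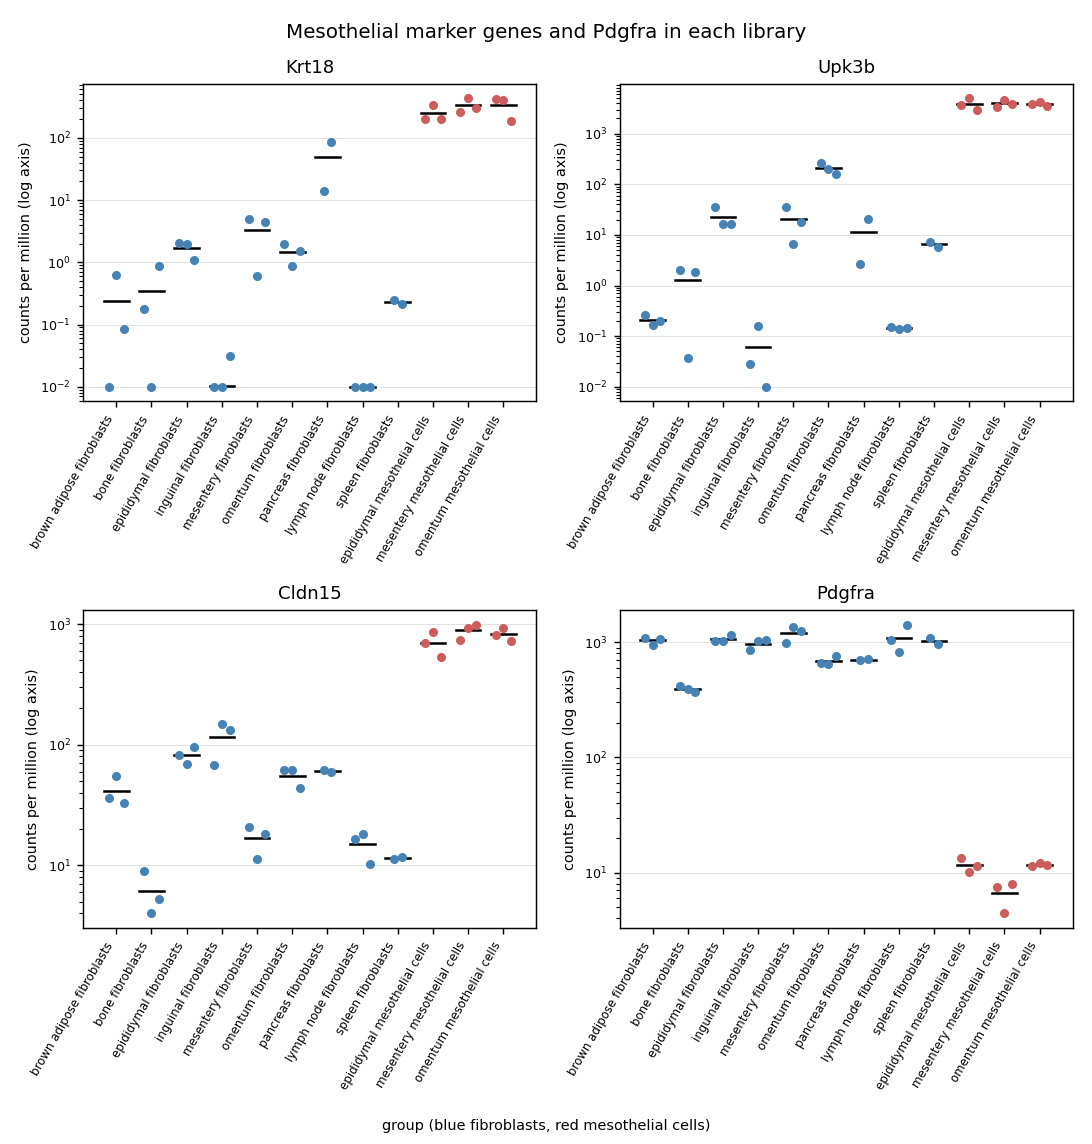
CPM of Krt18, Upk3b, Cldn15 and Pdgfra in each of the 34 libraries by group, on a logarithmic axis, with a bar at the group mean and values under 0.01 drawn at 0.01. Upk3b averaged 3869 in omentum mesothelial cells and 207 in omentum fibroblasts.

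Mesothelial cells of the 3 depots differed among themselves in 3167 genes (n = 3 libraries per depot). Omentum mesothelial cells held inflammatory chemokines at higher levels than mesentery cells, Cxcl3 (6.06 ± 0.73) and Cxcl2 (ENSMUSG00000058427, chromosome 5, 90903871 to 90905938, 4.58 ± 0.67, adjusted p = 6.51e-05) for neutrophil attractants, and Serpinb2 (5.71 ± 0.89) and Tnfaip2 (4.56 ± 0.37), both induced in inflammation. Of 19 myeloid growth factors and chemokines 6 were higher against the mesentery, 8 adjusted over the list alone (camera adjusted p = 4.04e-09), and 8 against epididymal fat, 9 adjusted over the list alone (adjusted p = 1.85e-09). They included Csf2 (4.31 ± 0.72), Ccl7 (2.86 ± 0.52) and Ccl2 (2.65 ± 0.54) in the former comparison and Il34 (2.12 ± 0.20), Il6 (3.28 ± 0.53) and Cxcl1 (2.93 ± 0.48) in the latter. Csf1 differed by 0.87 ± 0.35 against the mesentery (adjusted p = 0.15) and was higher than in epididymal cells by 1.47 ± 0.36. The former passed without omentum replicate 1 (1.21, adjusted p = 0.0304) and the latter did not without omentum replicate 2 (1.15, adjusted p = 0.0603). Wt1, Gata6 and Aldh1a1 had log2 differences of -0.35 ± 0.30, 0.16 ± 0.28 and 0.38 ± 0.21 against the mesentery and 0.26 ± 0.30, 0.22 ± 0.28 and -0.71 ± 0.21 against epididymal fat, none of them called. Without the libraries of at least 1000 acinar CPM, chosen after the data were seen and leaving 1 mesentery mesothelial library, the mesentery difference was 4.13 for Cxcl2, 4.57 for Serpinb2, 2.16 for Ccl7 and 2.08 for Ccl2, none of them called among the libraries left, and 1.70 for Csf1 (adjusted p = 0.035). Aldh1a2 was higher than in epididymal cells (1.76 ± 0.41), as were the retinoid genes Rdh10 (3.19 ± 0.26), Rarb (2.81 ± 0.39) and Stra6 (2.21 ± 0.50). Posterior Hox genes, which mark position along the body axis, were lower in the omentum, 5 of 8 paralogs 9 to 13 against the mesentery, 6 adjusted over the list alone (adjusted p = 1.69e-06), and 3 against epididymal fat, 5 adjusted over the list alone (adjusted p = 7.5e-05). Hoxc8 (-6.10 ± 0.40) and Hoxc6 (-4.13 ± 0.45) showed the same direction against the mesentery. The gut mesenchyme factor Nkx2-3 averaged 4.28 ± 1.21 CPM in mesentery cells and had no count in the others, at least 158-fold higher than in epididymal cells, and the stomach factor Barx1 averaged 4.73 ± 0.882 CPM in omentum cells, at least 174-fold higher than in epididymal cells. The flavin monooxygenase gene Fmo2 (-5.63 ± 0.34) and the sterol transporter gene Abcg5 (-5.58 ± 0.49) were lower in the omentum than in the mesentery. Each called gene named in this paragraph lay in every library of one depot beyond those of the other.

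Proliferation genes were higher in omentum than in mesentery mesothelial cells in 6 of 13 genes, 10 adjusted over the list alone (adjusted p = 1.19e-08, and adjusted p = 0.164 with an estimated correlation), with Rrm2 (1.54 ± 0.31) and Ccnb1 (2.11 ± 0.47). Neither was called without the libraries of at least 1000 acinar CPM, where 1 mesentery library is left and gives no spread of its own (1.70 and 2.62). Lymphoid stroma genes were higher in the omentum than in epididymal fat in 6 of 16 and lower in 1 (adjusted p = 5.68e-05), 7 higher when adjusted over the list alone, led by Ch25h (4.0 ± 0.50) and Vcam1 (2.66 ± 0.34). Between mesentery and epididymal cells 1075 genes differed, 508 higher and 567 lower in the mesentery, and the collagen VI genes Col6a5 (-4.42 ± 0.29) and Col6a6 (-4.26 ± 0.35) were lower there. Of 15 pancreatic acinar markers 14 were higher in the mesentery than in epididymal cells (adjusted p = 9.33e-25), and 13 in the omentum than in epididymal cells (adjusted p = 1.4e-05, and adjusted p = 0.425 with an estimated correlation). Those of the largest rises against epididymal cells that encode pancreatic products, Try5 (11.58 ± 2.56) and Rnase1 (8.74 ± 2.12), moved with them. Try5 lost its call without epididymal replicate 1 or 2 (adjusted p = 0.0531 and 0.0503), and Rnase1 without omentum replicate 1 (1.69, adjusted p = 0.769). The immunoglobulin gene Igkc (8.41 ± 2.0) was higher in the omentum than in the mesentery, but not called without mesentery replicate 1 (9.82, adjusted p = 0.0668) or without the libraries of at least 1000 acinar CPM, with 1 mesentery library left (12.35, adjusted p = 0.302). The leukocyte list passed upward in the omentum, with a median log2 fold change of 2.02 (adjusted p = 0.00334, and adjusted p = 0.521 with an estimated correlation), while edgeR called 0 of its 16 genes (DESeq2 1), with an unadjusted p under 0.05 for 5. Its summed level went the other way, with 637 to 781 CPM in omentum and 846 to 1864 CPM in mesentery libraries. Endothelial markers were lower in the omentum than in epididymal fat in 4 of 12 genes, 5 adjusted over the list alone (adjusted p = 0.016, and adjusted p = 0.565 with an estimated correlation). In all, 1324 genes differed between omentum and mesentery cells (606 higher in the omentum) and 2668 between omentum and epididymal cells (913 higher in the omentum). The former count was 845 without omentum replicate 2 and 868 without mesentery replicate 1, and the latter 1312 without omentum replicate 2. Fitted on their 6 libraries alone, omentum and epididymal cells differed in 1612 genes, 826 higher and 786 lower in the omentum, with a median log2 fold change over all genes of -0.02 in place of -0.24. Without the libraries of at least 1000 acinar CPM, and so with 1 mesentery library assumed to vary like the other groups, the omentum and mesentery count was 476 and the mesentery and epididymal count 522 (353 higher and 169 lower), and the omentum and epididymal split was 966 higher and 1143 lower. With no filter on low counts mesentery and epididymal cells differed in 1904 genes.

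Fibroblasts differed between the 9 tissues in 11308 of 25705 genes (25 libraries), and Hox and other regional transcription factors were among them. Hoxa10 averaged 34.9 ± 3.34 CPM in bone, 17.6 ± 0.631 in inguinal and 6.96 ± 0.887 in lymph node fibroblasts (n = 3 each), and at most 1.47 CPM, in the mesentery, in the other fibroblast groups. Hoxc10 averaged 40.3 ± 6.58 CPM in bone, 37.2 ± 2.88 in inguinal and 11.2 ± 1.73 in lymph node fibroblasts. Hoxc8 averaged 22.2 ± 1.47 CPM in epididymal and 10.5 ± 1.57 in mesentery fibroblasts but 0.198 ± 0.0924 CPM in the omentum, 0.446 ± 0.41 in the pancreas and 0.279 ± 0.308 in the spleen (n = 2 in the last pair). Tbx15, a factor of trunk and limb mesenchyme, averaged from 40.8 to 53.8 CPM in bone, lymph node, brown adipose and inguinal fibroblasts and at most 0.658 CPM in the other groups. Tcf21 averaged from 56.8 to 147 CPM in pancreas, spleen, omentum, epididymal and mesentery fibroblasts and at most 0.939 CPM in the rest. Wt1 averaged 189 ± 5.6 CPM in omentum, 61.7 ± 1.65 in spleen, 50.9 ± 2.18 in mesentery, 50.4 ± 15.5 in epididymal and 27.6 ± 2.4 in pancreas fibroblasts, and at most 0.501 CPM in the others. Aldh1a2 averaged 505 ± 35.3 CPM in omentum, 121 ± 21.2 in pancreas, 110 ± 25.5 in spleen and 92.1 ± 27.5 in mesentery fibroblasts, 21.5 ± 17.3 in bone and 15.2 ± 3.9 in epididymal fibroblasts, and at most 0.826 CPM in the others. Gata6 was highest in lymph node (45.6 ± 27.1 CPM) and lowest in bone fibroblasts (0.46 ± 0.207), and Csf1 was lowest in bone (91 ± 23.7) and pancreas (125 ± 54).

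**Figure D2:**
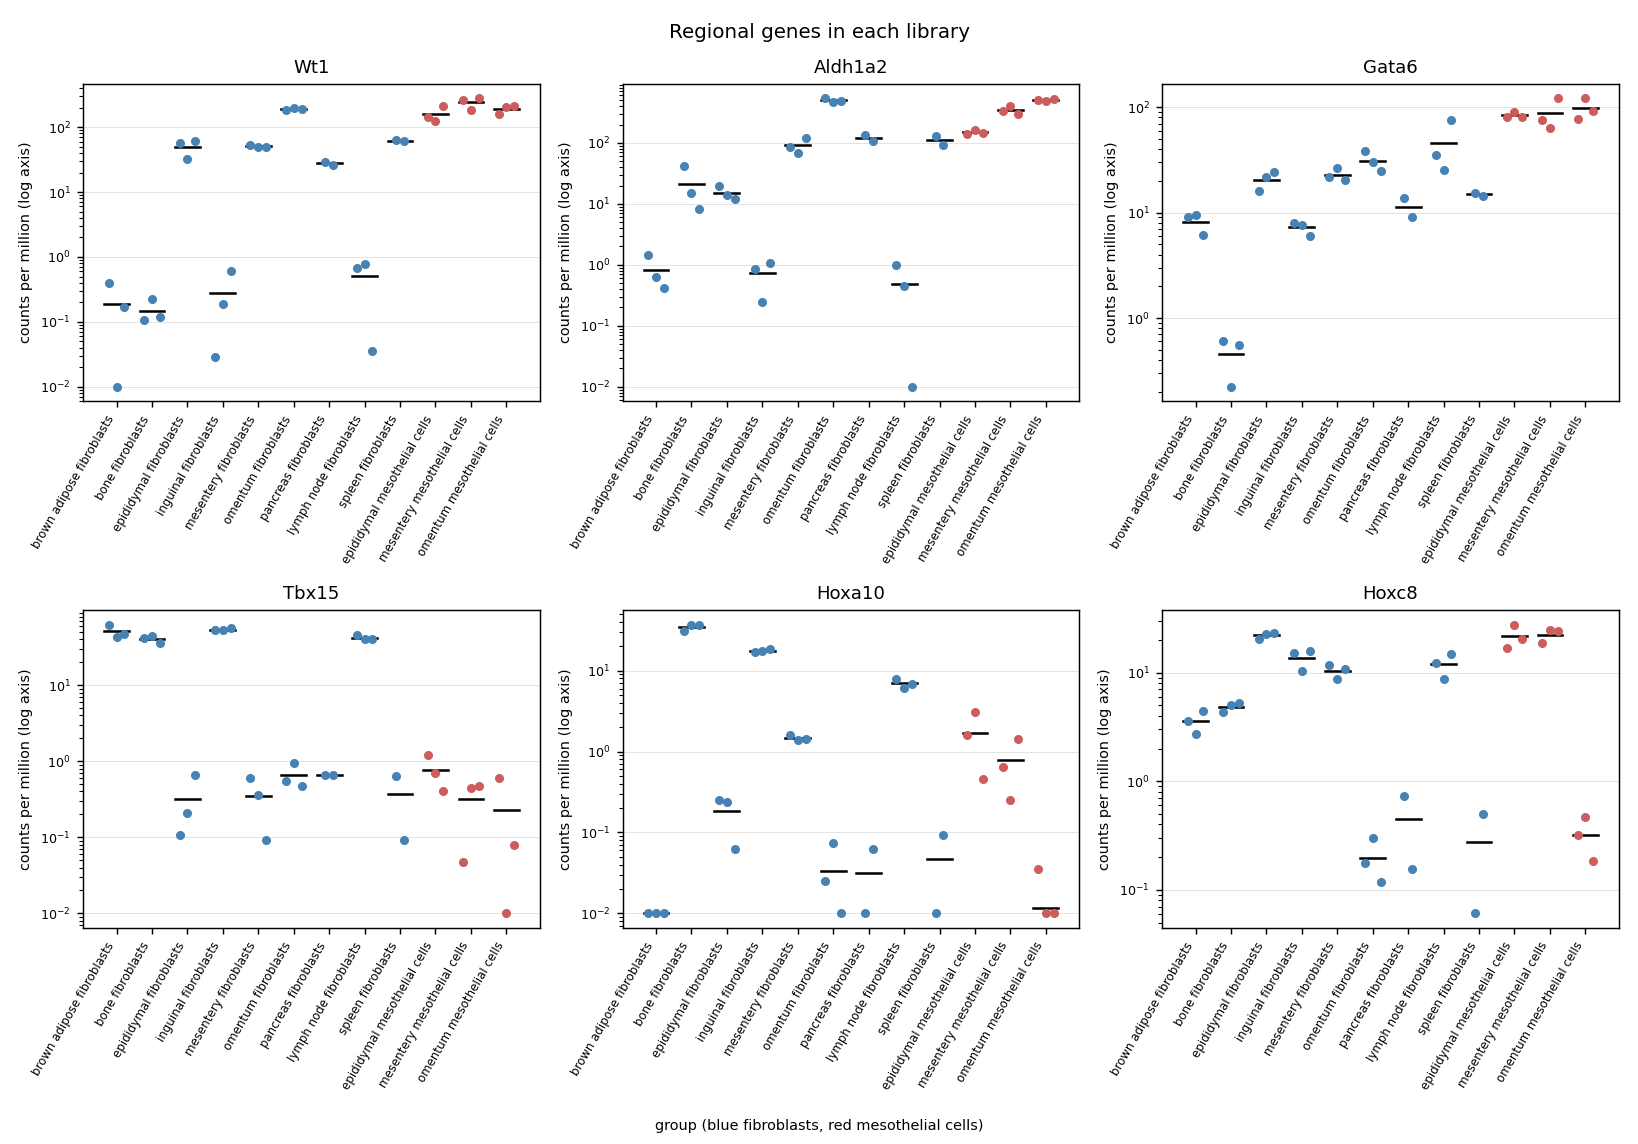
CPM of Wt1, Aldh1a2, Gata6, Tbx15, Hoxa10 and Hoxc8 in each of the 34 libraries by group, on a logarithmic axis, with a bar at the group mean and values under 0.01 drawn at 0.01. Wt1 averaged 189 in omentum fibroblasts and at most 0.501 in lymph node, inguinal, brown adipose and bone fibroblasts.

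Fibroblasts of the visceral fat depots were compared with those of the subcutaneous depots (n = 9 and 6 libraries), and 2116 genes differed, 1104 higher and 1012 lower in visceral fat (1412 and 791 with DESeq2). The p-values rest on the spread between libraries of the same tissue and do not measure how depots of a class vary. The subcutaneous class holds only inguinal fat and brown adipose tissue. Wt1 was higher by 8.41 ± 0.34 (adjusted p = 6.87e-19), and its partners in visceral mesenchyme Tcf21 (8.02 ± 0.42) and Aldh1a2 (6.84 ± 0.39) rose with it. Upk1b, a uroplakin gene of the mesothelial list, had no count in subcutaneous libraries and was at least 1400-fold higher in visceral fibroblasts, and Upk3b (8.62 ± 0.60) and the protease inhibitor gene Slpi (9.05 ± 1.23) were also among the largest rises. Others were Gdpd2 (7.59 ± 0.46), the microglial receptor gene Trem2 (7.19 ± 0.82), Tnfrsf19 (6.91 ± 0.42) and Hp (6.48 ± 0.45). The falls were led by the decoy receptor gene Il1r2 (ENSMUSG00000026073, chromosome 1, 40074079 to 40125231, -7.51 ± 0.25, adjusted p = 3.86e-24) and by the developmental factors Mab21l1 (-7.28 ± 0.34), Shox2 (-7.27 ± 0.36) and Tbx15 (-6.92 ± 0.29). The cadherin gene Cdh9 (-7.21 ± 0.40), the integrin gene Itgb7 (-7.12 ± 0.36), the matrix gene Thbs4 (-6.59 ± 0.56), the steroid and alcohol dehydrogenase genes Akr1c18 (-5.74 ± 0.37) and Adh7 (-5.41 ± 0.21) and the kinase gene Prkg2 (-5.05 ± 0.24) were also lower. In each of these genes every visceral library lay beyond every subcutaneous library. Gata6 (1.67 ± 0.20) was higher, while Aldh1a1 (0.55 ± 0.14) and Csf1 (-0.47 ± 0.22, adjusted p = 0.169) were not called.

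Of 16 mesothelial markers 15 were higher in visceral fibroblasts (camera adjusted p = 3.68e-25), including Nkain4 (5.52 ± 0.27) and Rspo1 (3.09 ± 0.26). Fibroblast matrix genes were lower in 9 of 16 (adjusted p = 4.15e-13), with Col1a2 (-2.14 ± 0.13) and Col3a1 (-1.90 ± 0.16) for fibrillar collagens. Mural cell markers, of pericytes and smooth muscle, were higher in 6 and lower in 1 of 10 genes (adjusted p = 0.000217), with Des (4.15 ± 0.40) and Myh11 (2.67 ± 0.42). Schwann cell markers were lower in 3 of 5 (adjusted p = 0.000501, and adjusted p = 0.0514 with an estimated correlation), with Mbp (-2.0 ± 0.20). Thermogenic genes were lower in 5 and higher in 1 of 10 (adjusted p = 0.0374, and adjusted p = 0.0923 with an estimated correlation), 2 higher when adjusted over the list alone, led by Lhx8 (-5.13 ± 0.46) and Cox8b (-4.44 ± 0.55). Lhx8 averaged 1.72 CPM in inguinal and 1.68 CPM in omentum fibroblasts, so these depots were alike in it. Cox8b averaged 3.51 and 0.0182 CPM in the same order. Leukocyte markers were higher in 4 of 16, 8 adjusted over the list alone (adjusted p = 5.02e-06, and adjusted p = 0.292 with an estimated correlation), with Cd74 (3.30 ± 0.58) and Lyz2 (2.53 ± 0.70). Acinar markers were higher in 4 of 15, 5 adjusted over the list alone (adjusted p = 1.67e-20, and adjusted p = 0.055 with an estimated correlation), with Cela1 (5.84 ± 0.94). Col4a6 (3.88 ± 0.22) was higher and Ccl8 (-3.71 ± 0.28) lower. Of the list members named here, Myh11, Mbp, Lhx8, Cd74, Lyz2 and Cela1 overlapped between visceral and subcutaneous libraries.

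Each tissue's fibroblasts were next compared with the mean of the other 8 fibroblast groups on the log scale, in which groups with a level near 0 weigh heavily. A tissue far above or below the others also shifts that mean for each of the rest. Bone did so for skeletal genes, lymph node for lymphoid stroma genes and pancreas for immediate early genes. Calls of these lists in other tissues may partly mirror that tissue. On simulated counts, the spleen and lymph node comparisons of this kind gave more false calls than the adjusted p threshold allows. The genes named among the largest changes of a tissue lay in each of its libraries beyond every library of the other tissues, while list members shared between tissues could overlap. Omentum fibroblasts (n = 3) had 1965 higher and 611 lower genes, and their median log2 fold change over all genes was 0.12 when fitted on the fibroblast libraries alone. Secreted immune signals were among the higher genes, with the B cell attractant Cxcl13 (ENSMUSG00000023078, chromosome 5, 95956951 to 95961068, 5.17 ± 0.28, adjusted p = 1.85e-13) at 3148 ± 720 CPM, Il6 (3.82 ± 0.28), Cxcl1 (2.69 ± 0.27), Csf3 (5.11 ± 0.59) and Il34 (2.13 ± 0.12) higher. Of 19 myeloid growth factors and chemokines 10 were higher (camera adjusted p = 1.71e-10), as were 6 of 12 complement genes, 7 adjusted over the list alone (adjusted p = 6.98e-11), among them C4b (2.11 ± 0.17) and C3 (1.67 ± 0.12). Wt1 (5.79 ± 0.20), Aldh1a2 (5.62 ± 0.24), Isl1 (6.52 ± 0.23), the retinol dehydrogenase gene Rdh10 (3.39 ± 0.14) and Gata6 (1.63 ± 0.20) were higher. Of the mesothelial markers 13 of 16 were higher, 14 adjusted over the list alone (adjusted p = 3.98e-20), with Upk3b (6.88 ± 0.33) and Lrrn4 (6.17 ± 0.31). The 5 largest rises were immunoglobulin genes, whose variable segments can share reads. Among them were Igkv12-89 (11.78 ± 0.87) and Igha (11.29 ± 0.53), which DESeq2 did not call (adjusted p = 0.118 and 0.133). Immediate early genes were higher in 6 of 16 (adjusted p = 0.00142, and adjusted p = 0.435 with an estimated correlation). Mural cell markers were higher in 3 and lower in 1 of 10, and endothelial markers in 2 and 1 of 12, in list tests that did not pass (adjusted p = 0.271 and 0.391). The immunoglobulin genes moved with 11 of 16 leukocyte markers, 14 adjusted over the list alone, such as Ms4a1 (3.61 ± 0.54) and Cd79b (3.97 ± 0.63) of B cells (adjusted p = 2.49e-07, and adjusted p = 0.233 with an estimated correlation). All 15 acinar markers were higher too (adjusted p = 3.96e-15, and adjusted p = 0.118 with an estimated correlation). Among them Pnlip averaged 254 CPM, against a mean of 959 over the other groups, which include the pancreas. The lower genes were led by Angptl1 (-6.52 ± 0.42), the small leucine-rich proteoglycan gene Aspn (-4.37 ± 0.30) and Duoxa1 (-4.45 ± 0.43). Skeletal and tendon genes were lower in 6 and higher in 1 of 21 (adjusted p = 2.45e-06).

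Mesentery fibroblasts (n = 3) had 563 higher and 336 lower genes (466 and 504 with DESeq2) than the other tissues. The granin Scg2 (ENSMUSG00000050711, chromosome 1, 79434669 to 79440120, 7.79 ± 0.45, adjusted p = 2.04e-13), the adhesion receptor gene Adgrv1 (4.68 ± 0.27), Iyd (3.60 ± 0.29) and the signalling ligand gene Wnt2b (2.83 ± 0.18) led the rises. Among the falls, Il1r2 (-3.91 ± 0.35), the cartilage gene Cnmd (-3.68 ± 0.51), Igfbp3 (-3.10 ± 0.30) and Amy1 (-3.55 ± 0.32) were the largest. The gut factor Nkx2-3 (7.32 ± 0.40), Tcf21 (4.58 ± 0.26), Hand2 (4.34 ± 0.30), Wt1 (3.66 ± 0.21) and Aldh1a2 (2.86 ± 0.26) were higher. In CPM, Aldh1a2 averaged 92.1, against a mean of 96.8 over the other groups. Lymphoid stroma genes were lower in 5 of 16, 6 adjusted over the list alone (camera adjusted p = 3.15e-06), with Cxcl13 (-3.73 ± 0.50) and Ccl19 (-2.76 ± 0.62). Ccl19 lost its call without replicate 2 or 3 (adjusted p = 0.0604 and 0.0551). Skeletal and tendon genes were lower in 4 and higher in 1 of 21 (adjusted p = 9.24e-09). The other groups include bone, which was high for these genes, and lymph node, which was high for lymphoid stroma genes. Mesothelial markers were higher in 11 of 16, 12 adjusted over the list alone (adjusted p = 7.96e-13), and acinar markers in 15 of 15 (adjusted p = 1.13e-21). The acinar gene Pnlip averaged 131 CPM, against a mean of 975 over the other groups, which include the pancreas.

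Epididymal fibroblasts (n = 3) had 643 higher and 497 lower genes (594 and 741 with DESeq2). The estrogen sulfotransferase gene Sult1e1 (ENSMUSG00000029272, chromosome 5, 87575969 to 87591594, 5.16 ± 0.22, adjusted p = 3.47e-16), at 1296 ± 33.8 CPM, and Mmd2 (6.18 ± 0.24), Anxa9 (3.19 ± 0.17), the angiotensinogen gene Agt (3.11 ± 0.17) and Hoxc8 (3.26 ± 0.19) led the rises. Chl1 (-5.90 ± 0.80), the bone morphogenetic protein gene Bmp3 (-4.03 ± 0.35), the retinoic acid hydroxylase gene Cyp26b1 (-3.96 ± 0.42) and Tmem176a (-3.44 ± 0.24) were among the largest falls. Basement membrane genes were higher in 6 of 14, with 1 lower when adjusted over the list alone (camera adjusted p = 1.73e-14), with Col4a6 (3.51 ± 0.17) and Lamb1 (1.32 ± 0.16). Hox genes of paralog groups 1 to 8 were higher in 6 of 20, 7 adjusted over the list alone (adjusted p = 7.9e-05, and adjusted p = 0.0761 with an estimated correlation). Lymphoid stroma genes were lower in 7 of 16 (adjusted p = 6.87e-05), against a mean that includes the lymph node. Mesothelial markers were higher in 12 of 16, 14 adjusted over the list alone (adjusted p = 2.99e-16). Wt1 (3.64 ± 0.21) and the retinaldehyde dehydrogenase gene Aldh1a3 (1.90 ± 0.15) were higher, while Aldh1a2 differed by -0.06 ± 0.34 (adjusted p = 0.99). Endothelial markers moved with these groups, 4 of 12 higher and 7 adjusted over the list alone (adjusted p = 0.000107, and adjusted p = 0.32 with an estimated correlation).

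Inguinal fibroblasts (n = 3) had 860 higher and 760 lower genes (597 and 1155 with DESeq2). Il1r2 (6.27 ± 0.19, adjusted p = 6.11e-26), at 1018 ± 74.7 CPM, Il18r1 (3.95 ± 0.20) and Adh7 (4.11 ± 0.17) were among the largest rises with Mab21l1 (4.90 ± 0.24) and Pcdh20 (4.06 ± 0.20), and Cadm1 (-5.13 ± 0.53), Hmcn1 (-4.36 ± 0.33) and Tmem204 (-3.76 ± 0.32) among the largest falls. Fibroblast matrix genes were higher in 6 of 16 (camera adjusted p = 3.38e-15), with Col3a1 (1.99 ± 0.16) and Col6a3 (1.69 ± 0.13). Posterior Hox genes were higher in 5 and lower in 1 of 8 (adjusted p = 5.29e-05), with Hoxc10 (6.81 ± 0.27) and Hoxa10 (6.14 ± 0.31). Fat cell genes Pparg (3.39 ± 0.29), Cd36 (3.45 ± 0.34) and Lpl (1.27 ± 0.17) were among 5 of 14 higher adipogenic genes (adjusted p = 0.00831, and adjusted p = 0.202 with an estimated correlation), beside 2 of 8 higher adipocyte markers. Wt1 (-4.81 ± 0.46) and Aldh1a2 (-4.98 ± 0.50) were lower. Schwann cell markers were higher in 3 of 5, 4 adjusted over the list alone (adjusted p = 1.99e-05), and mural cell markers lower in 5 of 10, 7 adjusted over the list alone (adjusted p = 2.55e-06).

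Brown adipose fibroblasts (n = 3) had 940 higher and 707 lower genes (628 and 974 with DESeq2). Thermogenic genes were higher in 4 of 10, 5 adjusted over the list alone (camera adjusted p = 0.00288), among them Zic1 (2.88 ± 0.26) and Lhx8 (4.63 ± 0.31), factors of the brown lineage. Morc1 (ENSMUSG00000022652, chromosome 16, 48431237 to 48630900, 8.60 ± 0.32, adjusted p = 2.46e-25), the integrin gene Itgb7 (5.75 ± 0.26), Angptl1 (4.54 ± 0.18), Lgi1 (3.57 ± 0.25) and Krtdap (3.17 ± 0.19) led the rises. The falls were led by the amino acid transporter gene Slc36a2 (-4.47 ± 0.43), Cxadr (-3.93 ± 0.42), Cd82 (-3.60 ± 0.28), Coch (-3.59 ± 0.54) and Nrp2 (-3.26 ± 0.26). Fibroblast matrix genes were higher in 8 of 16 (adjusted p = 1.54e-17). Immediate early genes, which respond within minutes to stimuli, were higher in 7 of 16 (adjusted p = 6.77e-08, and adjusted p = 0.164 with an estimated correlation), with Jun (1.63 ± 0.31) and Ier2 (1.5 ± 0.29). Their sum of 12216 to 18012 CPM overlapped that of every other fibroblast tissue except pancreas and spleen. The mean of the other groups includes the pancreas, with a sum of at most 1325 CPM. Tbx15 (4.32 ± 0.23) and Tbx5 (2.54 ± 0.21) were higher and Wt1 (-5.39 ± 0.48) and Aldh1a2 (-4.79 ± 0.49) lower. Skeletal muscle markers were higher in 3 of 10, 4 adjusted over the list alone (adjusted p = 0.0341, and adjusted p = 0.392 with an estimated correlation), with Acta1 (4.77 ± 0.48) at 8.71 CPM.

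Bone fibroblasts (n = 3) had 3293 higher and 1710 lower genes, and skeletal genes led the rises. Of 21 skeletal and tendon genes 19 were higher (camera adjusted p = 8.07e-31). The osteocalcin genes Bglap2 (ENSMUSG00000074486, chromosome 3, 88377736 to 88378699, 19.78 ± 0.22, adjusted p = 2.02e-30) and Bglap (18.93 ± 0.24), near-identical copies whose reads counting can split, averaged 17703 and 14793 CPM. Higher too were Ibsp (18.95 ± 0.31), the collagenase gene Mmp13 (17.73 ± 0.33), the cartilage collagen gene Col2a1 (14.87 ± 0.44), Dmp1 (12.22 ± 0.24) of osteocytes and Acan (11.60 ± 0.26) of cartilage. Type I collagen rose, with Col1a1 (5.21 ± 0.21) and Col1a2 (4.56 ± 0.11), but over the matrix list 5 genes were higher and 3 lower, its median of -0.53 and mean of 0.60 differed in sign, and camera gave an adjusted p of 0.481. Basement membrane genes were lower in 10 of 14 (adjusted p = 6.11e-11) and complement genes in 8 of 12, with 2 higher (adjusted p = 7.88e-07). Posterior Hox genes were higher in 6 of 8 (adjusted p = 6.79e-05), with Hoxa10 (7.26 ± 0.29) and Hoxc10 (6.94 ± 0.27), and Shox2 (5.81 ± 0.24) rose too. The retinoid genes Cyp26a1 (9.37 ± 0.43) and Crabp2 (7.65 ± 0.25) were higher and Aldh1a1 (-2.57 ± 0.20) lower. Gata6 (-5.19 ± 0.39), Wt1 (-5.77 ± 0.52), Csf1 (-1.68 ± 0.30) and the estrogen sulfotransferase gene Sult1e1 (-8.56 ± 0.58) were lower. All 10 skeletal muscle markers were higher (adjusted p = 2.62e-16), with Acta1 (13.42 ± 0.37) at 1797 ± 1398 CPM, as were 5 of 6 erythroid markers, 6 adjusted over the list alone (adjusted p = 0.00535, and adjusted p = 0.292 with an estimated correlation). Of the leukocyte markers 8 of 16 were higher and 1 lower, 9 higher when adjusted over the list alone, in a list test that did not pass (adjusted p = 0.072), with Coro1a (2.94 ± 0.48) and Ptprc (1.87 ± 0.57), the transcript of the excluded CD45, higher. Ptprc was not called with DESeq2 or without bone replicate 2 or 3 (adjusted p = 0.0586, 0.0562 and 0.0782), nor without replicates 1 and 2 together (adjusted p = 0.134).

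Pancreas fibroblasts (n = 2) had 2223 higher and 594 lower genes (1164 and 774 with DESeq2), and digestive enzyme transcripts led the rises. All 15 acinar markers were higher (camera adjusted p = 2.35e-32), with Cel (ENSMUSG00000026818, chromosome 2, 28555795 to 28563403, 12.71 ± 0.84, adjusted p = 1.17e-13) at 14419 ± 14067 CPM and Pnlip (12.47 ± 0.81). The 5 largest rises, Amy2a1 (14.49 ± 1.55), Gp2 (13.44 ± 1.13), Try5 (13.37 ± 1.08), Amy2a4 (12.84 ± 0.95) and Amy2a3 (12.84 ± 0.95), encode acinar products, the last pair near-identical copies. Immediate early genes were lower in 13 of 16 (adjusted p = 8.07e-31), among them Fos (-3.85 ± 0.33) at 322 ± 20.2 CPM, Fosb (-5.57 ± 0.63), Zfp36 (-3.97 ± 0.36) and Socs3 (-3.56 ± 0.36). The inflammatory genes Cxcl1 (-5.84 ± 0.63), Cxcl2 (-6.39 ± 1.06), Il6 (-5.44 ± 0.67) and Ccl7 (-4.29 ± 0.63) and the hyaluronan synthase gene Has1 (-5.67 ± 0.74) were lower with them. Complement genes were lower in 4 and higher in 1 of 12, 2 adjusted over the list alone (adjusted p = 2.34e-07), with Cfb (-2.09 ± 0.21) and C2 (-1.96 ± 0.18). Aldh1a2 (3.30 ± 0.29), Wt1 (2.66 ± 0.26) and the gut factors Nkx2-3 (6.71 ± 0.48) and Hand2 (5.06 ± 0.31) were higher and Csf1 (-1.17 ± 0.35) lower, the last not called without replicate 1 (-0.78). In CPM, Wt1 averaged 27.6, against a mean of 44.1 over the other groups. Markers of other cell types rose beside these groups, with epithelial markers higher in 5 of 6 (adjusted p = 7.01e-07), including Cdh1 (7.39 ± 0.36) and Epcam (6.89 ± 0.49). Leukocyte markers were higher in 14 of 16, 16 adjusted over the list alone (adjusted p = 0.0443, and adjusted p = 0.688 with an estimated correlation), and endothelial markers in 9 of 12, 10 adjusted over the list alone (adjusted p = 0.0824). The leukocyte markers summed to 22.2 CPM in replicate 1 and 465 CPM in replicate 2, against 11.3 to 49.2 CPM in inguinal, brown adipose and mesentery fibroblast libraries, 413 to 581 in omentum and 407 to 890 in lymph node libraries. The acinar transcripts summed to 47548 CPM in replicate 1 and 169540 CPM in replicate 2. Without replicate 1 the count of called genes fell from 2817 to 1862.

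**Figure D3:**
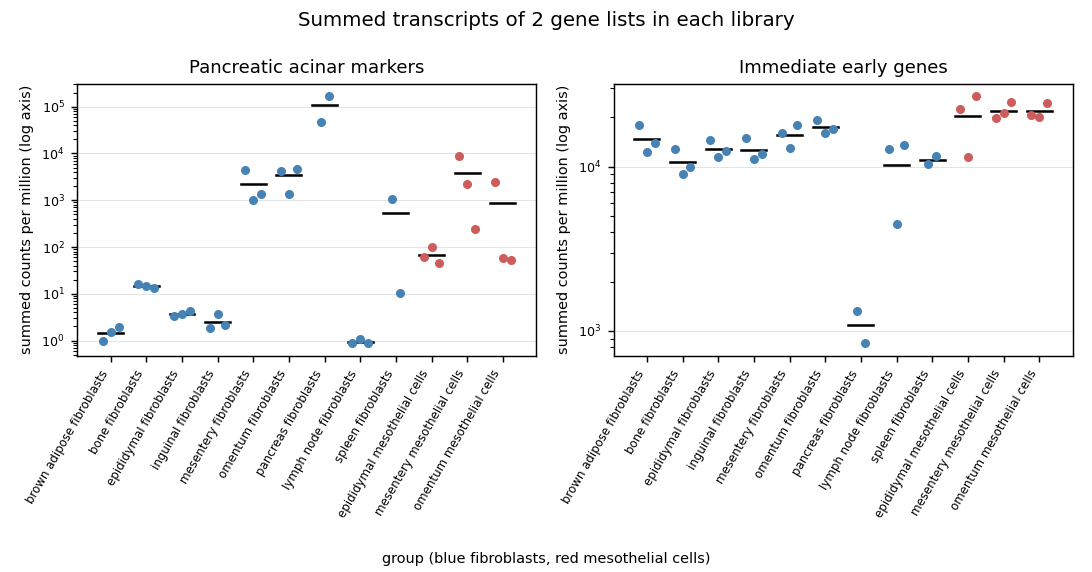
Sums of CPM over the 15 acinar markers and over the 16 immediate early genes in each of the 34 libraries by group, on a logarithmic axis, with a bar at the group mean. The acinar sum was 169540 CPM in pancreas replicate 2 and 8766 CPM in mesentery mesothelial replicate 1.

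Lymph node fibroblasts (n = 3) had 2396 higher and 1832 lower genes. Genes of lymphoid stroma, which recruits and sustains lymphocytes, were higher in 13 of 16 (camera adjusted p = 1.27e-18), with Bst1 (8.19 ± 0.24), the B cell survival factor gene Tnfsf13b (3.45 ± 0.11) and Clu (6.16 ± 0.20). The T cell zone chemokine gene Ccl21a (ENSMUSG00000094686, chromosome 4, 42772860 to 42773993, 11.80 ± 0.95, adjusted p = 5.32e-10), whose near-identical copies may share its reads, averaged 25985 ± 5252 CPM. The other largest rises were Apol11a (11.98 ± 0.39), the desmosomal cadherin gene Dsc3 (11.35 ± 0.41), Apol11b (11.33 ± 0.35) and Sohlh2 (10.68 ± 0.35). Cxcl12 (4.41 ± 0.22) and Il33 (2.96 ± 0.14) rose among 9 higher and 2 lower of 19 myeloid growth factors and chemokines (adjusted p = 0.00254, and adjusted p = 0.234 with an estimated correlation). Complement genes C4b (3.52 ± 0.16) and C3 (2.33 ± 0.12) were higher. The prostacyclin synthase gene Ptgis (-5.75 ± 0.21), Gprc5a (-5.56 ± 0.53), the transporter gene Slc6a13 (-5.28 ± 0.43) and the chemokine scavenger gene Ackr4 (-5.10 ± 0.28) were among the largest falls. Fibroblast matrix genes were lower in 12 of 16 (adjusted p = 4.15e-13), with Fbn1 (-2.12 ± 0.20) and Sparc (-1.66 ± 0.16). Proliferation genes were lower in 10 and higher in 1 of 13 (adjusted p = 8.92e-05, and adjusted p = 0.357 with an estimated correlation). Gata6 (2.26 ± 0.19), Nr2f1 (4.43 ± 0.20) and Foxf1 (3.83 ± 0.22) were higher, and Wt1 (-3.76 ± 0.41), Aldh1a2 (-5.61 ± 0.54) and Aldh1a1 (-1.33 ± 0.18) lower. Mural cell markers rose beside the lymphoid genes in 8 of 10, with 1 lower (adjusted p = 1.18e-07), including Rgs5 (6.31 ± 0.31) at 492 ± 104 CPM and Kcnj8 (5.11 ± 0.17). Endothelial markers were lower in 9 of 12, 10 adjusted over the list alone (adjusted p = 5.39e-05, and adjusted p = 0.292 with an estimated correlation). Leukocyte markers were higher in 5, 6 adjusted over the list alone, and lower in 1 of 16, in a list test that did not pass (adjusted p = 0.203), and summed to 407 to 890 CPM in the lymph node libraries.

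Spleen fibroblasts (n = 2) had 891 higher and 107 lower genes (549 and 185 with DESeq2). Lymphoid stroma genes were higher in 7 of 16 (camera adjusted p = 5.16e-07), with the addressin gene Madcam1 (ENSMUSG00000020310, chromosome 10, 79664559 to 79668537, 6.26 ± 0.38, adjusted p = 3.58e-18), Ccl19 (4.04 ± 0.41) and Bst1 (3.64 ± 0.30). In CPM, Ccl19 (401 against a mean of 1012 over the other groups) and Bst1 (12.3 against 25.9) were lower in spleen. Regional transcription factors were higher in 12 and lower in 4 of 29, 5 adjusted over the list alone (adjusted p = 0.000222), with Hand2 (4.0 ± 0.36), Tcf21 (3.71 ± 0.30) and Wt1 (3.97 ± 0.23). Retinoid metabolism genes were higher in 5 of 19, 6 adjusted over the list alone (adjusted p = 0.000654), with the retinyl ester synthase gene Lrat (3.74 ± 0.31), Aldh1a2 (3.15 ± 0.29) and Aldh1a1 (1.02 ± 0.17). Aldh1a1 lay at the threshold and was not called with DESeq2 or another scaling, nor without spleen replicate 1 (0.97) or bone replicate 3 (0.99). Complement genes were higher in 3 of 12 (adjusted p = 7.06e-09). The largest rises were the carbonic anhydrase gene Car1 (10.08 ± 0.40), the renin gene Ren1 (6.46 ± 0.23), Coch (6.31 ± 0.24), the scavenger receptor gene Stab2 (4.79 ± 0.38) of sinusoids and Col4a6 (4.70 ± 0.18). Only Procr (-1.57 ± 0.22) and Map7d1 (-1.08 ± 0.27) met the naming rule among the falls, the latter called only with both spleen libraries in the fit (adjusted p = 0.334 and 0.116 without replicate 1 or 2). All 6 erythroid markers were higher (adjusted p = 3.28e-11), with Hba-a1 (4.82 ± 0.53) at 25.6 ± 26.4 CPM, and the globin copies share reads where counting splits them. Acinar markers were higher in 3 of 15, 12 adjusted over the list alone, in a list test that did not pass (adjusted p = 0.592), with sums of 1077 CPM in replicate 1 and 10.2 CPM in replicate 2. The count of 998 genes fell to 567 without replicate 1 and to 476 without replicate 2, where the remaining library is assumed to vary like the other groups.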

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

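The test of whether the mesothelial-fibroblast difference varies between depots was planned, and no test in this part was chosen after the result was seen. These results are listed because that test, edgeR's quasi-likelihood F-test of the interaction, called them at an adjusted p under 0.05 with a range of log2 differences over the 3 depots of at least 1 (n = 3 libraries per group). It called 2812 genes. Of 71 genes named in the mesothelial comparisons 32 were among them. The range was 2.24 for Wt1 and 3.29 for Aldh1a2, which were alike in both omentum cell types and higher in mesothelial cells elsewhere. Among mesothelial markers it was 2.64 for Cldn15 and 2.0 for Nkain4. Among developmental transcription factors it was 6.30 for Isl1, 5.63 for Hand2, 3.30 for Prrx1 and 1.99 for Ebf2, while Gata6 (0.37, adjusted p = 0.767) and Tcf21 (1.92, adjusted p = 0.104) were not called. Fat and retinoid genes that were called had ranges of 5.01 for Pparg, 1.65 for Lpl, 3.77 for Dhrs9 and 1.84 for Adh1. Immune genes had ranges of 6.26 for Cxcl13, 5.74 for Cd74, 4.41 for Clu, 2.47 for Il7 and 2.47 for Il33, and complement genes of 1.70 for C2, 1.74 for Cfb and 2.26 for Cd55. For matrix and basement membrane genes they were 2.88 for Lum, 1.98 for Pcolce2, 1.52 for Col6a3, 1.43 for Col4a1, 1.49 for Nid1 and 1.23 for Lamc1. Other ranges were 4.96 for Kcnip1, 3.13 for Fam151a and 3.09 for Galnt16. Stmn4 (10.35), Duoxa1 (9.48) and Mybpc2 (7.83) had no count in a group of a depot, so their fitted ranges depend on the prior count and are no bounds. No group holds enough libraries to look for a single library far from the others. A difference between the depots themselves stays open for each of these genes.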

How the results depend on the processing

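The fits without the 2 pancreas libraries, without libraries of at least 1000 acinar CPM, without bone replicates 1 and 2 together and with marker genes of other cell types removed before scaling, and the list tests with a replicate block, were tests chosen after the results were seen; the others were planned. Over 20 counts of called genes, 477 of 490 alternative values lay within 1.5 times the reported count, including each one under RLE scaling, DESeq2, the replicate block, removal of marker genes, and without the pancreas or both bone libraries. These are total counts, and with DESeq2 the split into higher and lower genes shifted. It turned to more lower than higher genes in mesentery, epididymal, inguinal and brown adipose fibroblasts. The higher count fell in pancreas and spleen, as given above. Of 334 gene values in the text 306 kept their direction and their call under every alternative run, no called value changed direction, and 21 of 319 called values lost their call under at least 1 alternative.

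Without libraries of at least 1000 acinar CPM 1 mesothelial and 1 fibroblast library of the mesentery remained, each assumed to vary like the other groups, and the counts were 2535 for mesothelial cells against fibroblasts in the mesentery, 476 for omentum against mesentery and 522 for mesentery against epididymal mesothelial cells. All 3 omentum fibroblast libraries exceeded that acinar limit, so no comparison that uses them was run without the carrying libraries. These include visceral against subcutaneous fat and each tissue comparison, and the fit covered 47 of the 334 gene values. With no filter on low counts mesentery and epididymal mesothelial cells differed in 1904 genes, and with only the groups compared omentum and epididymal mesothelial cells differed in 1612 genes. The cause of these last shifts was not tested. With an estimated correlation 70 of the 171 list tests passed. Leaving out 1 library at a time, the count ran from 1767 to 3418 for the difference between depots, from 845 to 1428 for omentum against mesentery, from 1312 to 2792 for omentum against epididymal mesothelial cells, from 1862 to 3063 for pancreas and from 476 to 1068 for spleen fibroblasts. For the other counts it stayed within 1.5 times. Rnase1 gave no value with only omentum and epididymal mesothelial cells in the fit, where it was filtered out.

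The values that changed sign lay near 0 and were called under no alternative. In omentum mesothelial cells against fibroblasts, Aldh1a2 was -0.04 with RLE scaling, -0.07 with no filter, -0.10 with only the groups compared, -0.04 with DESeq2 and -0.04 with marker genes removed, and from -0.17 to 0.07 when leaving out 1 library. Wt1 was -0.02, -0.05, -0.09, -0.02 and -0.02 in the same order, and from -0.09 to 0.14. Aldh1a2 in epididymal fibroblasts was 0.01 with no filter, 0.41 without the pancreas libraries, 0.11 without both bone libraries, and from -0.28 to 0.08 when leaving out 1 library. Gata6 in omentum against mesentery mesothelial cells was -0.07 without libraries of at least 1000 acinar CPM, and from -0.03 to 0.48 when leaving out 1 library. The cause was not tested.

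With the replicate number as a block the counts moved little, for example from 1075 to 1067 for mesentery against epididymal mesothelial cells, from 1324 to 1367 for omentum against mesentery and from 5503 to 5455 for the mean mesothelial comparison. The block ended the call of Aldh1a1 in spleen fibroblasts (1.02 without it), and changed no other call of a gene in the text. With the block 173 of the list tests passed instead of 171, and none was lost. The 2 gained were myeloid growth factors and chemokines in visceral against subcutaneous fibroblasts (adjusted p from 0.0547 to 0.0355) and proliferation genes in inguinal fibroblasts (adjusted p from 0.101 to 0.0337), and with the block and an estimated correlation neither passed (adjusted p = 0.356 and 0.635). With the block and an estimated correlation 72 passed, and matrix genes in the mean mesothelial comparison no longer did (adjusted p from 0.0486 to 0.0585). Depth limits genes with few counts: with 0 counts on a side, up to 3 counts remain possible, and a group of 2 libraries adds little to the estimate of the spread.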

Other observations

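The splits of the samples and the tests of the 3 patterns weighed below were tests chosen only after the results were seen, and the list tests were planned. Several planned gene lists not described above passed camera with both the preset and an estimated correlation. Adipogenic genes were lower in mesothelial cells than in fibroblasts in each depot, namely in 11 of 14 in the omentum (adjusted p = 2.05e-10, and 0.00682 with an estimated correlation). They were lower in 10, with 1 higher, in the mesentery (adjusted p = 1.44e-07, and 0.0144) and in 7 in epididymal fat (adjusted p = 1.71e-06, and 0.0196). Fibroblast matrix genes were lower in mesothelial cells in 12 of 16 in the mesentery (adjusted p = 9.44e-12, and 0.0291 with an estimated correlation) and in 8 of 16 in epididymal fat (adjusted p = 1.26e-10, and 0.0364). Among fibroblasts, against means that include the lymph node, lymphoid stroma genes were lower in bone in 8 of 16 with 1 higher (adjusted p = 4.5e-05, and 0.0157). They were lower in pancreas in 7 with 1 higher (adjusted p = 0.000153, and 0.02) and in brown adipose tissue in 7 with 2 higher (adjusted p = 0.000247, and 0.0225). Mesothelial markers were lower in inguinal fibroblasts in 7 of 16 with 1 higher (adjusted p = 1.86e-12, and 0.021). In brown adipose fibroblasts they were lower in 6 of 16 (adjusted p = 9.38e-11, and 0.0306). Posterior Hox genes were lower in brown adipose fibroblasts in 2 of 8 (adjusted p = 1.16e-06, and 0.0144), and mural cell markers there in 3 of 10, 4 adjusted over the list alone (adjusted p = 3.67e-06, and 0.0159).

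Group labels of the compared libraries were reassigned to other splits and the called genes counted again. For comparisons of 3 with 3 libraries the 10 splits are too few for a share under 0.05. The real split called the most genes, so 1 of 10 reached its count, in each of these comparisons. For mesothelial cells against fibroblasts the counts were 4342 for the real split and at most 0 for the others in the omentum, 4701 and 53 in the mesentery and 6358 and 8 in epididymal fat. Beside that 0 from edgeR, up to 4011 genes had an unadjusted p under 0.05, and DESeq2 was not run on the splits. Between mesothelial cells they were 1324 and 57 for omentum against mesentery, 2668 and 669 for omentum against epididymal fat, and 1075 and 208 for mesentery against epididymal fat. For the mean mesothelial difference 1 of 80 splits reached 5503 genes (highest other 3651). For its variation between depots 2 of 80 reached 2812 (highest other 4167). These splits mixed cell types and depots, so the shares speak only against all libraries being interchangeable. They cannot tell whether the difference varies between depots by chance. Among mesothelial depots 1 of 100 reached 3167 (highest other 2215), which speaks against interchangeable libraries among the depots. For visceral against subcutaneous fat 1 of 100 reached 2116 (highest other 860), where the splits mixed libraries of all the tissues compared. Among fibroblast tissues, with 50 splits each, 1 reached 5003 for bone (highest other 1736) and 1 reached 4228 for lymph node (highest other 1348). For omentum 2 reached 2576 (highest other 3195) and for inguinal fat 2 reached 1620 (highest other 1710). For brown adipose tissue 2 reached 1647 (highest other 2264). In these last 3 a split called more genes than the real one, and 1 further such split of 50 would have brought the share over 0.05. For mesentery 4 reached 899 (highest other 4102) and for epididymal fibroblasts 3 reached 1140 (highest other 2452), shares of 0.05 or more. These splits drew on all 25 fibroblast libraries, whose tissues differed in 11308 genes. A split can therefore hold libraries of another tissue, such as bone, and count its differences. High counts such as 4102 are thus no measure of chance, and these shares decide about it for no single tissue.

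Acinar transcripts appeared outside the pancreas, with at least 100 CPM in 12 libraries, up to 8766 CPM in mesentery mesothelial replicate 1 and 4704 CPM in omentum fibroblast replicate 3, against 0.992 CPM in brown adipose replicate 1. Expression by the sorted mesothelial cells and spleen fibroblasts is argued against, because the highest library held 46.1 (omentum mesothelial), 35.4 (mesentery mesothelial) and 106 (spleen) times the acinar sum of the lowest. For the sorted omentum and mesentery fibroblasts the fold between libraries, at most 4.37 times, cannot tell their own expression from an outside source. Their markers stood near the proportions of the pancreas libraries, which RNA or cells from acinar tissue predict. The SD of log2(library/pancreas mean) over the markers was 0.179 to 0.545, and r with the pancreas was 0.971 to 0.994. RNA or cells from acinar tissue are a candidate source: over the carrying libraries, the SD over the 15 markers of log2(library/pancreas mean) had a median of 0.354 (0.179 to 2.86, the highest in epididymal mesothelial replicate 2), and the most abundant, Cela2a, averaged 847 CPM in omentum fibroblasts, 758 CPM in mesentery mesothelial cells and 27619 CPM in pancreas fibroblasts, followed in the mesentery by Try4 at 535 CPM. The Epcam-negative sort would remove intact acinar cells but not free RNA, and a difference between the tissues themselves stays open as untested.

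Omentum fibroblasts carried mesothelial transcripts, with Upk3b at 207 CPM (5.35% of the omentum mesothelial level), Krt19 at 91.7 CPM (5.06%) and Nkain4 at 188 CPM (14.6%). Mesothelial cells or their RNA as the source of Wt1 are argued against, because Wt1 lay at 98.3% of its mesothelial level (95.4% in the lowest library), while no other of the 14 markers at 100 CPM or more exceeded 17.6% in any library. For the remaining markers, mesothelial cells or their RNA in the sorted fibroblasts cannot be told apart from expression by the fibroblasts: the median share was 5.09%, and 1 marker, Krt18 at 0.432%, lay under 0.2 of it in each library, while Krt8 at 0.872% and Msln at 0.877% did so on the group means. The gate on PDGFRA would remove mesothelial cells but not their free RNA. An omentum fibroblast that itself expresses part of the mesothelial list stays open as a hypothesis, untested.

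Immediate early transcripts were low in pancreas fibroblasts, with a median log2 fold change of -3.53 (SD 1.45 over 16 genes), and their sum was at most 1325 CPM in the pancreas libraries and at least 4496 CPM in every library of the other groups. After 586 genes at least 8-fold higher in the pancreas were removed before scaling, the median was -3.50, with 13 of 16 genes still called lower. The scaled fall thus does not rest on those genes. TMM scaling already trims extreme genes, and the genes removed were chosen in these libraries. This test could therefore hardly move the median, and it does not decide whether transcripts of other cells took counts. A lower share of fibroblasts in the sort is argued against as the whole source, because the median of the fibroblast matrix genes was -0.45 (SD 0.78). Differences in handling between tissues may lower such genes too, and the tables do not separate them from the tissue itself, which stays open and untested.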
